A study of Mus musculus with 16 samples.

How the data were processed

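Total RNA of freshly sorted cells was made into libraries with a NEBNext Ultra II RNA kit, per the labels' protocols, and the deposited table holds 1 column of values for each of the 16 libraries and 27179 rows, each an Entrez gene number, most with a symbol. Its values are a normalized signal that the authors deposited, read counts per gene divided by 1 factor per library. The submitters' processing notes name Trim Galore 0.4.1, HISAT2 2.0.1, featureCounts 1.4.6 and DESeq2 1.6.3 and the mouse builds GRCm38 and mm10, with no role or order; the strand setting, the gene annotation and the treatment of reads that match several genes are not given in the sources used here. Genes that overlap, antisense genes and near-identical copies may therefore share reads, and the values of such genes are uncertain. The columns of the smooth muscle libraries carry a longer abbreviation, SMLCs, than the sample titles; the 4 columns so headed were taken as SMCs replicates 1 to 4 because the other 12 column names matched the other titles and the numbers matched.

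The values in each column were whole multiples of 1 step, and 100% of the values above 0 came out as whole reads within 0.01. Multiplying each step by a median-of-ratios size factor computed from the recovered reads gave 1 for all 16 libraries, so the scaling is the one DESeq2 uses by default. The recovered totals, from 9.20 to 27.5 M reads, are the depth of the libraries; at the median depth of 21.6 M reads a normalized count of 10 rests on about as many reads, so low values carry a large counting error. FIPs replicate 1 and APCs replicate 2 passed this check too, at steps of 0.989 and 1.007. They were kept out of the count test because steps so near 1 leave little difference between the values and whole reads. Of the rows, 1275 had no symbol and were kept under their Entrez number; they held between 0.0812% and 0.135% of the values of each library. Pairs of libraries of the same population differed by a chi-square of 5.25 to 28.7 per degree of freedom, far above counting noise, so no library was counted as a copy of another.

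Genes with a normalized value of at least 10 in at least 4 of the 16 libraries were tested, 15024 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend) on log2(value + 1), with the 4 populations as groups in 1 model of all 16 libraries and no other term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Because of the added 1, fold changes of low genes are understated. The contrasts were the 6 pairs of populations, and MLCs and SMCs each against the mean of APCs and FIPs; a gene counted as a population's own when it was called higher there in all 3 of its pairs. A call against the mean of APCs and FIPs does not say that the population differs from both in that direction. The words rose and fell refer to the first population of a contrast, and values after ± are SDs over libraries unless SE is written.

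Gene lists were tested with camera at its preset correlation of 0.01, and again with the correlation estimated from the data, in 3 main comparisons: APCs against FIPs, and MLCs and SMCs against the progenitor mean. With an estimated correlation 2 of 29 lists held in the first comparison, 1 in the second and 0 in the third, where 13, 6 and 16 passed with the preset one. The lists were 26 lists of named genes (adipocyte differentiation and lipid storage, committed preadipocyte, Dpp4-positive interstitial progenitor, collagen and fibrosis, inflammatory cytokine and NF-kB, mesothelial, contractile smooth muscle, pericyte, cell cycle, dissociation stress and immediate early, imprinted growth network, Wnt, hedgehog, Notch, BMP and TGF-beta, retinoid metabolism, cholesterol synthesis, complement, and markers of endothelial, macrophage and myeloid, lymphocyte, erythroid, mature adipocyte, Schwann, skeletal muscle and epididymal epithelial cells) and 3 sets taken by gene name (ribosomal protein, oxidative phosphorylation, mitochondrially encoded). The table names mitochondrial protein genes without the usual prefix, so a list of them was added after the data were seen. Counts of members called are given over all genes and adjusted over the list alone.

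The genes named were set by a rule. For each main comparison it took the 10 largest rises and 10 largest falls among called genes with a mean of at least 100 on the higher side, no overlap between the libraries of the sides, and a symbol that is neither predicted nor mitochondrial. It also took up to 4 members of each list with the smallest adjusted p, the 5 leading genes of each population, and 8 panel genes (Pdgfrb, Pdgfra, Ly6c1, Cd9, Dpp4, Pparg, Msln, Acta2). Pecam1 was named in addition after its values were seen, and not every gene the rule gives is named. Coordinates are 1-based RefSeq gene spans on GRCm38, matched by Entrez number for 25275 of the rows.

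The tests were checked on simulated negative binomial counts with the real means and library sizes, in which 67 genes changed 1.5-fold, 67 changed 3-fold and 66 changed 8-fold. At a 3-fold change limma called 62 of 67 genes for APCs against FIPs (14910 genes tested), 64 of 67 for MLCs against progenitors (14906 genes) and 64 of 67 for SMCs (14897 genes); at 8-fold it called 64, 65 and 65 of 66, and at 1.5-fold, under the fold limit, 0, 0 and 2 of 67. Of unchanged genes it called 3 of 14693, 1 of 14690 and 6 of 14678. For APCs against FIPs edgeR on 14 libraries called 59 of 67 genes at 3-fold and 64 of 66 at 8-fold. Each simulated gene had its mean over all 16 libraries and a dispersion smoothed over genes, directions were random, and 20 more genes were doubled. The real populations differed in far more genes, often more in 1 direction, so these rates need not hold for the data.

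The tests, lists, naming rule and these alternatives were chosen before the data were examined: the replicate number as a block, pseudocounts of 0.1 and 8, no filter and a filter at 50, libraries scaled to equal totals, quantile normalization, a fit of only the groups compared, library weights, no fold limit, an estimated correlation for the lists, and leaving out each library. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM) on the whole reads recovered from 14 libraries, and a fit without APCs replicate 4 and SMCs replicate 3. Transcript lengths came from GENCODE transcripts and were used for 1 check of the closing section.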

Results

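RNA was sequenced from 4 sub-populations of Pdgfrb-expressing cells sorted by flow cytometry from the epididymal white fat of C57BL/6 mice at postnatal day 7, an age at which this depot is still forming. Pdgfrb codes for a platelet-derived growth factor receptor that marks mural cells and adipose progenitors. The sorted cells were adipocyte precursors (APCs), progenitors of fibro-inflammatory character (FIPs), cells resembling mesothelium, the epithelium that lines the fat pad (MLCs), and smooth muscle cells (SMCs). Each population had 4 libraries, 16 in all, and whether the 4 came from separate animals or sorts is not stated in the labels, so p-values measure the spread between these libraries, which may be technical. The reads behind the deposited values ranged from 9.20 to 27.5 M reads per library, with a median of 21.6 M. SMCs replicate 3, with 9.20 M reads, and APCs replicate 4, with 11.2 M, were the shallowest libraries. The questions the design sets are how the APC and FIP progenitors differ from each other, and how MLCs and SMCs differ from both.

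The MLCs stood furthest from the other populations. The first principal component, with 65.8% of the variance, separated MLCs from the rest, the second, with 14.8%, set SMCs apart, and the third, with 8.49%, parted APCs from FIPs. On the first component SMCs (-4.71 to 7.20) lay between the progenitors (-78.35 to -68.74) and MLCs (142.25 to 146.12). Pearson correlations across genes lay between 0.971 and 0.993 within populations, and had medians of 0.963 between APCs and FIPs, 0.927 between APCs and SMCs, 0.856 between MLCs and SMCs, and 0.798 between APCs and MLCs (genes are not independent replicates). The fourth component, with 2.49%, placed APCs replicate 4 away from the other APC libraries.

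**Figure D1:**
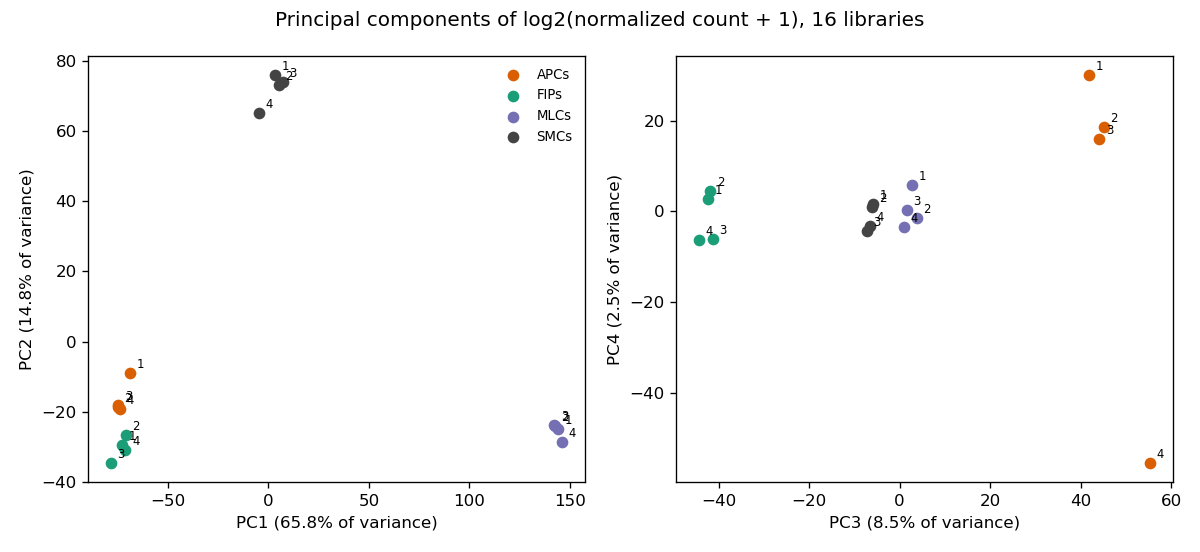
Each point is 1 library, numbered by replicate and coloured by population; the axes are principal components of log2(normalized count + 1), with the percent of variance of each. MLCs lie apart on the first component (65.8%), with SMCs between them and the progenitors. SMCs lie apart on the second (14.8%), APCs and FIPs at opposite ends of the third (8.49%), and APCs replicate 4 apart on the fourth (2.49%).

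Of 15024 genes tested, 8645 were called in none of the 6 pairwise contrasts (limma, Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold). APCs and FIPs were the closest pair with 1566 genes, 785 higher in APCs and 781 higher in FIPs. APCs and SMCs differed in 2590 genes, 569 of them higher in APCs, and FIPs and SMCs in 2693 genes, 691 of them higher in FIPs. MLCs differed in 4440 genes from APCs, in 4671 from FIPs and in 4185 from SMCs, and the numbers higher in the other population were 1776, 1876 and 2026. Quantile normalization moved the share of calls that were higher in APCs than in SMCs from 21.97% to 44.5%, and the share higher in FIPs than in SMCs from 25.7% to 45.6%. Scaling to equal totals moved the share higher in FIPs than in MLCs from 40.2% to 28.6%, and quantile normalization moved it to 49.3%, with 49.8% higher in APCs than in MLCs.

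Genes used to mark these populations separated them unevenly. Pdgfrb averaged 4717 ± 166 normalized counts in APCs, 2862 ± 198 in FIPs, 3787 ± 411 in SMCs and 457 ± 28.0 in MLCs (SD, n = 4 each). Pdgfra, a sister receptor that marks fibroblasts and progenitors, was at 20555 ± 248 in APCs, 22966 ± 975 in FIPs and 23838 ± 1968 in SMCs, against 471 ± 44.8 in MLCs, and the SMC level did not differ from the progenitor mean (log2 fold change 0.13 ± 0.06 SE, limma adjusted p = 0.0663). Ly6c1, a surface antigen, was at 2760 ± 268 in FIPs and 94.5 ± 27.4 in APCs. Cd9, a tetraspanin, was at 2001 ± 124 in MLCs and 1287 ± 86.8 in SMCs, and at 146 ± 9.85 or less on average in both progenitors. Dpp4, a cell surface peptidase, was higher in FIPs (2053 ± 275) than in APCs (52.6 ± 26.6) and was highest in MLCs (8805 ± 405). Pparg, the transcription factor that drives fat cell formation, was at 1282 ± 56.3 in APCs and 444 ± 47.7 in FIPs. Msln, coding for mesothelin, was at 14396 ± 598 in MLCs and 641 ± 37.5 in SMCs. Acta2, coding for smooth muscle actin, was at 4537 ± 1304 in SMCs and 1428 ± 231 in MLCs, and among APC libraries it was at 2388 in replicate 4 and between 156 and 221 in the others.

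**Figure D2:**
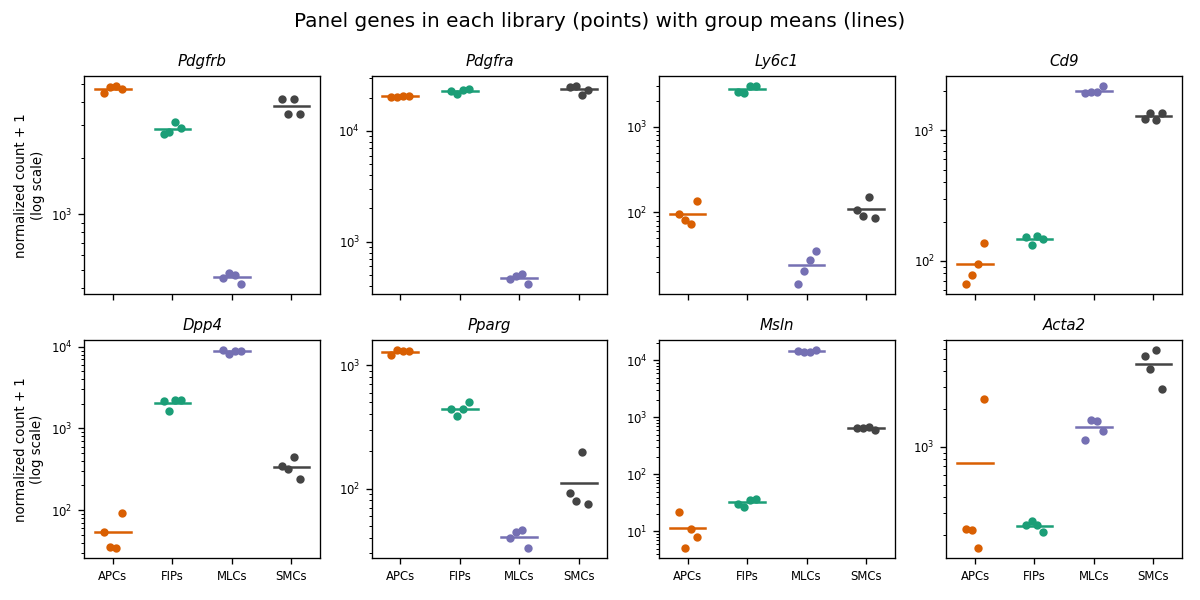
Normalized count + 1 (log axis) of 8 panel genes in each of the 16 libraries; points are libraries and lines the group means. Pdgfra was at about the same level in APCs, FIPs and SMCs and low in MLCs, and Acta2 in APCs replicate 4 (2388) lay above the other 3 APC libraries.

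APCs differed from FIPs by lipid storage genes such as Plin1 and Adipoq, which were higher in APCs, and by genes of Dpp4-positive interstitial progenitors such as Limch1 and Pi16, which were higher in FIPs. Plin1, coding for the lipid droplet coat protein perilipin 1 (Entrez gene 103968; GRCm38 chromosome 7, 79721164 to 79732904, a protein-coding gene), averaged 1607 ± 210 normalized counts in APCs and 38.7 ± 6.19 in FIPs (SD, n = 4 each), a 40.7-fold difference. Akr1c18, coding for a progesterone-metabolizing enzyme (Entrez gene 105349; chromosome 13, 4132615 to 4150646), was at 4.28 ± 5.25 in APCs and 277 ± 28.7 in FIPs, and Wnt10b, coding for a Wnt ligand that restrains fat cell formation (Entrez gene 22410; chromosome 15, 98770712 to 98778206), at 8.72 ± 4.91 and 596 ± 53.6. The other 9 genes with the largest rise in APCs were Car3, the carbonic anhydrase of fat and muscle, Mmd2, Lgals12, coding for a lectin of fat cells, Reep6, Cnmd, Mmp28, Adipoq, coding for adiponectin, Smoc1 and Tenm4, with log2 fold changes from 3.90 to 5.31. The other 8 with the largest fall were Bmp7, a ligand of the bone morphogenetic protein family, Dact2, Edn1, coding for endothelin 1, Limch1, Sema3e, Dpp4, Ackr2, a scavenging chemokine receptor, and Cmah, with log2 fold changes from -5.70 to -4.96.

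The adipocyte differentiation list rose in APCs. 15 of its 24 genes rose and 1 fell, and the counts adjusted over the list alone were also 15 and 1 (camera adjusted p = 1.42e-09, and adjusted p = 0.1 with an estimated correlation). Plin1 and Car3 led it, Lipe, coding for hormone-sensitive lipase, rose by 1.90 ± 0.11 (log2 ± SE), and Mgll, coding for monoglyceride lipase, fell by 2.52 ± 0.09. Of 7 measured mature adipocyte markers 6 rose, 6 also adjusted over the list alone (adjusted p = 1.43e-05, and adjusted p = 0.0573 with an estimated correlation). Adipoq (log2 4.24), Plin1, Cidec (2.65) and Lipe are in both lists. The summed level of those adipocyte markers was 2436 ± 291 in APCs, 173 ± 14.2 in FIPs, 313 ± 26.3 in MLCs and 929 ± 438 in SMCs. Of 15 measured committed preadipocyte genes 6 rose and 2 fell, 7 and 2 adjusted over the list alone (adjusted p = 0.00116, and adjusted p = 0.1 with an estimated correlation). Apoe (log2 2.39) and Col15a1 (2.07) rose. Adamts5 (-1.51) and Col5a3 (-1.42) fell. The pericyte list, of genes of the cells that wrap capillaries, had 10 of 15 genes higher in APCs and none lower, the same adjusted over the list alone (adjusted p = 1.32e-07, and adjusted p = 0.000885 with an estimated correlation). Gucy1a1 and Gucy1b1, coding for the subunits of soluble guanylate cyclase, rose by 2.88 and 2.28, and Notch3 by 1.31. Abcc9 was at 0.95, under the fold limit. Cell cycle genes were higher in APCs, 13 of 31 with none lower over all genes and adjusted over the list alone (adjusted p = 4.35e-17, and adjusted p = 0.1 with an estimated correlation). Rrm2 (1.47), Top2a (1.15), Cdk1 (1.15) and Kif11 (1.06), which act in DNA synthesis and mitosis, were among them.

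The interstitial progenitor list fell in APCs against FIPs. 16 of 18 genes fell and none rose, with the same counts adjusted over the list alone (adjusted p = 3.86e-20, and adjusted p = 0.000144 with an estimated correlation). On the log2 scale Limch1 was at -5.54, Pi16 at -4.01, Sema3c at -2.29 and Mfap5 at -2.21. Of the 28 collagen and fibrosis genes 5 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.00294, and adjusted p = 0.413 with an estimated correlation). Fn1, coding for fibronectin (-2.12), Fbn1 (-1.98) and Ccn1 (-1.38) fell. Fbln1 rose by 1.05. Of 18 imprinted growth genes 3 fell and 1 rose (adjusted p = 0.000148, and adjusted p = 0.15 with an estimated correlation), adjusted over the list alone 3 and 1. The 3 that fell were Cdkn1c (-1.52), Igf2 (-1.48) and H19 (-1.29, and -0.58 with quantile normalization, under the fold limit). Grb10 was at -0.61. The inflammatory list did not pass the test (2 of 22 fell and 1 rose, also adjusted over the list alone; adjusted p = 0.138, and adjusted p = 0.0341 without APCs replicate 4 and SMCs replicate 3), although Ptgs2 (-1.64) and Il6 (-1.25) fell. Cxcl2 (-0.89) and Nfkbia (-0.38) stayed under the fold limit.

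Among the signalling lists, the Wnt list and the BMP and TGF-beta list held genes that moved in opposite directions between APCs and FIPs. Of 18 Wnt genes 4 rose, among them Wnt4 (3.31) and Rspo3 (1.45), and 5 fell, among them Wnt10b (-6.08) and Sfrp2 (-2.62), with the same counts adjusted over the list alone (adjusted p = 0.69, median log2 fold change -0.23). In the BMP and TGF-beta list 4 of 19 genes rose and 4 fell, also adjusted over the list alone (adjusted p = 0.205). Tgfbi rose by 1.18, Bmp7 (-5.70) and Tgfbr2 (-1.47) fell, and Tgfbr1 was at 0.76. Of 13 Notch genes 6 rose and none fell, also adjusted over the list alone (adjusted p = 0.0249, and adjusted p = 0.296 with an estimated correlation), including Notch1 (2.17), Heyl (1.75) and Notch3. Notch2 was at -0.62. None of the 10 hedgehog genes was called over all genes or adjusted over the list alone, with Gas1 at 0.66, Boc at 0.64 and Smo at 0.20 (adjusted p = 0.0478, and adjusted p = 0.448 with an estimated correlation). In the contractile list 4 of 19 genes rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.241). Itga8 rose by 3.14 and Mylk by 1.35, Mustn1 fell by 1.93, and Tpm1 was at -0.63. Of 20 mesothelial genes 11 were lower in APCs and 1 higher, the same adjusted over the list alone (adjusted p = 0.0483, and adjusted p = 0.627 with an estimated correlation). Summed, the list was higher in APCs, at 6389 ± 225 against 4854 ± 328 in FIPs. Krt8 (-3.502) and Krt18 (-2.65, and -0.91 and not called with a pseudocount of 8) fell, Cldn15 (1.92) rose, and Nkain4 was at 0.59. No dissociation stress gene was called over all 20 or adjusted over the list alone (adjusted p = 0.591), with Klf6 at -0.81, Myc at -0.64, Atf3 at -0.41 and Klf4 at -0.41.

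Scaling the libraries to equal totals moved the median log2 fold change of all genes between APCs and FIPs by 0.24, raised the share of calls higher in APCs from 50.1% to 67.5%, and ended the Notch list's call (adjusted p = 0.162), and quantile normalization ended the collagen list's (adjusted p = 0.641). Leaving out single libraries moved the adjusted p of the hedgehog list between 0.0121 and 0.0757 and that of the mesothelial list between 0.00762 and 0.0971, and with pseudocounts of 0.1 and 8 the mesothelial list was not called (adjusted p = 0.0639 and adjusted p = 0.0954), so neither side of the threshold was fixed.

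MLCs differed from the progenitors by mesothelial genes such as Msln and Upk3b, which were higher, and by genes such as Postn, Lum, H19 and Igf2, which were lower. Against the mean of APCs and FIPs, 4520 genes were called, 2736 higher and 1784 lower in MLCs (limma, Benjamini-Hochberg). Upk1b, coding for a uroplakin (Entrez gene 22268; chromosome 16, 38773182 to 38800203), averaged 9360 ± 114 normalized counts in MLCs and 10.5 ± 6.70 over the 8 progenitor libraries, a log2 fold change of 9.91 ± 0.31 (SE, adjusted p = 3.1e-16). Msln (Entrez gene 56047; chromosome 17, 25748613 to 25754378) rose by 9.66. The other 8 genes with the largest rise were Pkhd1l1, Lrrn4, Upk3b, Chst4, Slpi, coding for a secreted protease inhibitor, Krt7, a keratin of simple epithelia, Tmem151a and Bnc1, with log2 fold changes from 9.21 to 9.89. Postn, coding for the matrix protein periostin (Entrez gene 50706; chromosome 3, 54359267 to 54391041), fell by 7.83 ± 0.08, from 170335 ± 63392 to 709 ± 103 normalized counts (adjusted p = 8.2e-23). Among the others with the largest fall were Lrrc17, Aspn, the imprinted noncoding RNA H19, Dpt, Lum, coding for the collagen-binding protein lumican, Ccl11, coding for eotaxin, Penk, coding for proenkephalin, and the imprinted gene Zim1, with log2 fold changes from -7.82 to -6.97.

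All 20 mesothelial genes rose in MLCs, over all genes and adjusted over the list alone (camera adjusted p = 3.01e-13, and adjusted p = 0.068 with an estimated correlation). Lrrn4 rose by 9.73, Upk3b by 9.63, Ezr, coding for the membrane linker ezrin, by 6.77 and Nkain4 by 4.03. The summed level of the mesothelial list was 222276 ± 4115 in MLCs, 25902 ± 4188 in SMCs, 6389 ± 225 in APCs and 4854 ± 328 in FIPs. Cell cycle genes were higher in MLCs, 25 of 31 with none lower, also adjusted over the list alone (adjusted p = 4.03e-09, and adjusted p = 0.404 with an estimated correlation), such as Cdc20 (1.81), Top2a (1.45), Rrm2 (1.43) and Kif11 (1.22). Of 18 imprinted growth genes 9 fell and 1 rose, the same adjusted over the list alone (adjusted p = 9.67e-07, and adjusted p = 0.101 with an estimated correlation). H19 was at -7.62, Zim1 at -6.97, Igf2 at -6.43 and Mest at -3.28. Of 15 committed preadipocyte genes 11 fell and 1 rose, also adjusted over the list alone (adjusted p = 6.72e-07, and adjusted p = 0.0489 with an estimated correlation), with Sparcl1 at -6.38, Gdf10 at -5.79, Col4a1 at -4.36 and Col4a2 at -3.81. Interstitial progenitor genes fell in 10 of 18 cases and rose in 3, adjusted over the list alone the same (adjusted p = 0.0392, and adjusted p = 0.378 with an estimated correlation). Summed, the list in MLCs lay below FIPs but above APCs (39187 ± 652, against 132787 ± 7598 and 30567 ± 1405). Pi16 (-6.14), Cd55 (-4.14), Fap (-3.54) and Mfap5 (-3.17) fell, although Dpp4, which names that list, rose by 4.80. Of 28 collagen and fibrosis genes 11 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.73 with an estimated correlation), with Fbn1 at -3.08, Col5a2 at -1.51 and Loxl1 at -1.501 beside Postn.

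Lists without a group call in MLCs still held large single changes. Of 24 adipocyte differentiation genes 10 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.0542). Lpl, coding for lipoprotein lipase (-5.98), Pparg (-4.23) and Cebpa (-3.502) fell, and Mgll rose by 2.16. Of 22 inflammatory genes 10 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.153), with Ccl11 at -7.17, Il6 at -4.98 and Vcam1 at -1.66, and Ptgs2 at 2.45. Contractile genes rose in 9 of 19 cases and fell in 2, adjusted over the list alone as well (adjusted p = 0.187). Myh11, coding for smooth muscle myosin, rose by 4.09 and Tpm1 by 1.68, and Itga8 fell by 5.50. Of 15 pericyte genes 5 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.442), with Gucy1a1 at 3.41, Vtn at -6.30, Notch3 at -4.36 and Ednra at -4.33. Of 18 Wnt genes 9 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.847, median log2 fold change 0.82 and mean -0.15). Dkk3 rose by 3.90. Sfrp1 (-4.98), Rspo3 (-4.93) and Dkk2 (-4.70) fell. Notch genes rose in 4 of 13 cases and fell in 5 (adjusted p = 0.311), hedgehog genes in 1 and 3 of 10 (adjusted p = 0.968, median -0.09, mean -0.47 and an upward test), and BMP and TGF-beta genes in 6 and 3 of 19 (adjusted p = 0.95, median -0.01, mean 0.24 and a downward test), and these counts were the same adjusted over the list alone. Among them Notch1 (-4.36), Heyl (-4.16), Jag1 (-1.43), Gli2 (-2.05) and Ltbp1 (-5.09) fell. Cdon (1.498), Bmp4 (5.16), Id1 (2.41) and Smad6 (1.72) rose. Of 20 dissociation stress genes 3 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.158), with Hspa1b at 1.54, Hspa1a at 1.16, Zfp36 at -1.43 (-0.89 with quantile normalization, under the fold limit) and Socs3 at -2.26.

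Quantile normalization moved the share of calls higher in MLCs from 60.5% to 50.5% and the median of all genes by -0.12, scaling to equal totals moved that median by 0.21, and under quantile normalization the collagen list (adjusted p = 0.591) and the interstitial progenitor list (0.142) were no longer called. Without APCs replicate 4 the interstitial progenitor list had an adjusted p of 0.0749, and the adipocyte list lay between 0.0419 and 0.0749 as single libraries were left out. The adipocyte list was called in 9 of those fits, and with equal totals, a pseudocount of 8 and the replicate block.

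SMCs differed from the progenitors by genes such as Myh11, Hhip, Gli1 and Upk3b, which were higher, and by genes such as Ccl11, Il6 and Idi1, which were lower. Against the mean of APCs and FIPs, 2524 genes were called, 1980 higher and 544 lower in SMCs (limma, Benjamini-Hochberg). Hhip, coding for a hedgehog-binding protein that hedgehog signalling induces (Entrez gene 15245; chromosome 8, 79965850 to 80058060), averaged 1410 ± 998 normalized counts in SMCs and 11.4 ± 4.99 over the 8 progenitor libraries, a log2 fold change of 6.70 ± 0.31 (SE, adjusted p = 1.02e-12). Elfn2 (Entrez gene 207393; chromosome 15, 78667333 to 78718771) rose by 7.02, the sodium leak channel gene Nalcn by 6.85 and Cntnap3 by 6.76. The remaining 6 of the 10 largest rises were Pkhd1l1, Upk1b, Lrrn4, Upk3b, Tmem151a and Dhrs9, at log2 fold changes from 5.94 to 6.93, and all but Dhrs9 were also among the 10 largest rises in MLCs. Dhrs9 too was higher in MLCs (1452 normalized counts) than in SMCs (198). Pcdh20, coding for a protocadherin (Entrez gene 219257; chromosome 14, 88464743 to 88471396), fell by 4.11 ± 0.13, from 1513 ± 736 to 79.1 ± 20.7 normalized counts. Ptx3, coding for a secreted pattern recognition protein, was at -3.94, Ccl11 at -3.93 and Tnfaip6, coding for a hyaluronan-binding protein, at -3.44. The remaining 6 of the 10 largest falls were Ifi207, Ebf2, coding for a transcription factor of fat progenitors, Efhd1, Nell1, Adamtsl3 and Tmeff2, at log2 fold changes from -3.43 to -3.12.

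Of 19 contractile genes 13 rose in SMCs and none fell, the same adjusted over the list alone (camera adjusted p = 1.82e-07, and adjusted p = 0.0602 with an estimated correlation). Myh11 rose by 3.99 and Tpm2 by 1.48, and Tpm1 was at 0.81. The summed level of the contractile list was 30124 ± 3046 in SMCs, 30528 ± 391 in MLCs, 17393 ± 2090 in APCs and 13820 ± 463 in FIPs. Mesothelial genes rose in 17 of 20 cases with none lower, also adjusted over the list alone (adjusted p = 5.94e-14, and adjusted p = 0.0602 with an estimated correlation). Lrrn4 rose by 6.18, Upk3b by 6.07, Ezr by 4.41 and Nkain4 by 2.44. In the hedgehog list 4 of 10 genes rose and none fell, also adjusted over the list alone (adjusted p = 0.000191, and adjusted p = 0.11 with an estimated correlation), Hhip together with the pathway target Gli1 (2.93), the receptor gene Ptch1 (2.90) and the co-receptor gene Boc (1.26). Of 15 pericyte genes 7 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.0783 with an estimated correlation). Summed, the pericyte list in SMCs lay above FIPs but not above APCs (8926 ± 870, against 3821 ± 158 and 9539 ± 686). Gucy1a1 rose by 2.47, Ednra, an endothelin receptor gene, by 2.10 and Cspg4 by 1.71, and Vtn fell by 3.10. Of 18 Wnt genes 7 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0236, and adjusted p = 0.0783 with an estimated correlation), with Dkk3 at 2.95, Wnt9a at 1.57, Wnt5a at 1.31 and Sfrp2 at -1.85. BMP and TGF-beta genes rose in 5 of 19 cases and fell in 1, adjusted over the list alone as well (adjusted p = 0.0648), with Ltbp2 at 4.36, Bmp4 at 3.43, Chrdl1 at 1.89 and Id3 at -1.03 (-0.99 without APCs replicate 3 and -0.93 without SMCs replicate 1, under the fold limit).

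Of 22 inflammatory genes 11 fell in SMCs and 2 rose, the same adjusted over the list alone (adjusted p = 5.09e-05, and adjusted p = 0.345 with an estimated correlation). Ccl11, Il6 (-3.07) and Cxcl1 (-2.07) fell, and the alarmin gene Il33 rose by 2.26. Cholesterol synthesis genes fell in 5 of 20 cases with none higher, also adjusted over the list alone (adjusted p = 3.19e-08, and adjusted p = 0.1 with an estimated correlation), with Idi1 at -1.75, Sc5d at -1.41, Insig1 at -1.37 and Hmgcs1 at -1.17. Of 18 interstitial progenitor genes 6 fell and none rose, the same adjusted over the list alone (adjusted p = 9.93e-05, and adjusted p = 0.0602 with an estimated correlation). Summed, the list in SMCs lay below FIPs but above APCs (39042 ± 1184, against 132787 ± 7598 and 30567 ± 1405). Opcml (-1.36) and Fap (-1.15) fell, and Cd55 (-0.93) and Cd248 (-0.87) stayed under the fold limit. Of 15 committed preadipocyte genes 5 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.000191, and adjusted p = 0.0777 with an estimated correlation). Bmper (-2.996), Lama4 (-1.82) and Col5a3 (-1.596) fell, and Mgp, coding for matrix Gla protein, rose by 3.54. Of 24 adipocyte differentiation genes 7 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.201), with Pparg at -2.89, Plin1 at -2.30, Acsl1 at -1.51 and Mgll at 1.25. Plin1 in SMCs lay below APCs only (53.0 ± 21.1, against 1607 ± 210 in APCs and 38.7 ± 6.19 in FIPs). Collagen and fibrosis genes rose in 5 of 28 cases and fell in 5, the same adjusted over the list alone (adjusted p = 0.663). Tnc, coding for tenascin C, rose by 5.17 and Tgfb3 by 1.497, Postn fell by 1.55, and Loxl1 was at -0.83. Imprinted growth genes fell in 3 of 18 cases and Notch genes in 2 of 13 with 2 higher, also adjusted over the list alone (adjusted p = 0.0744 and adjusted p = 0.852, the Notch median 0.12 and mean 0.10 with a downward test). H19 (-2.03), Mest (-1.85), Igf2 (-1.26, and -0.88 with quantile normalization) and Notch1 (-1.12) fell and Hey2 rose by 1.81 (0.95 with a pseudocount of 8). Under these alternatives Igf2 and Hey2 were not called. No cell cycle gene was called over all 31 or adjusted over the list alone, although the list lay below other genes (adjusted p = 0.037, and adjusted p = 0.679 with an estimated correlation), with Mcm4 at -0.58, Ccna2 at -0.48, Mcm3 at -0.39 and Mcm6 at -0.37. Of 20 dissociation stress genes 2 fell, also adjusted over the list alone (adjusted p = 0.00296, and adjusted p = 0.393 with an estimated correlation), including Myc (-1.33). Socs3 (-0.86), Hspa1a (0.76) and Hspa1b (0.93) stayed under the fold limit.

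Quantile normalization moved the share of calls higher in SMCs from 78.4% to 56.3%, ended the call of the dissociation stress list (adjusted p = 0.863) and called the collagen list (adjusted p = 0.00918). It also lost the call of the cell cycle list (adjusted p = 0.0876) and called the BMP and TGF-beta list (adjusted p = 0.0117). With equal totals 5 lists were no longer called: pericyte and Wnt (adjusted p = 0.0569 each), cell cycle and Schwann cell (adjusted p = 0.0603 each) and complement (adjusted p = 0.064). The adjusted p of the cell cycle list lay between 0.0122 and 0.103 as single libraries were left out, and passed 0.05 without APCs replicate 2, FIPs replicate 1, SMCs replicate 2 or SMCs replicate 4.

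**Figure D3:**
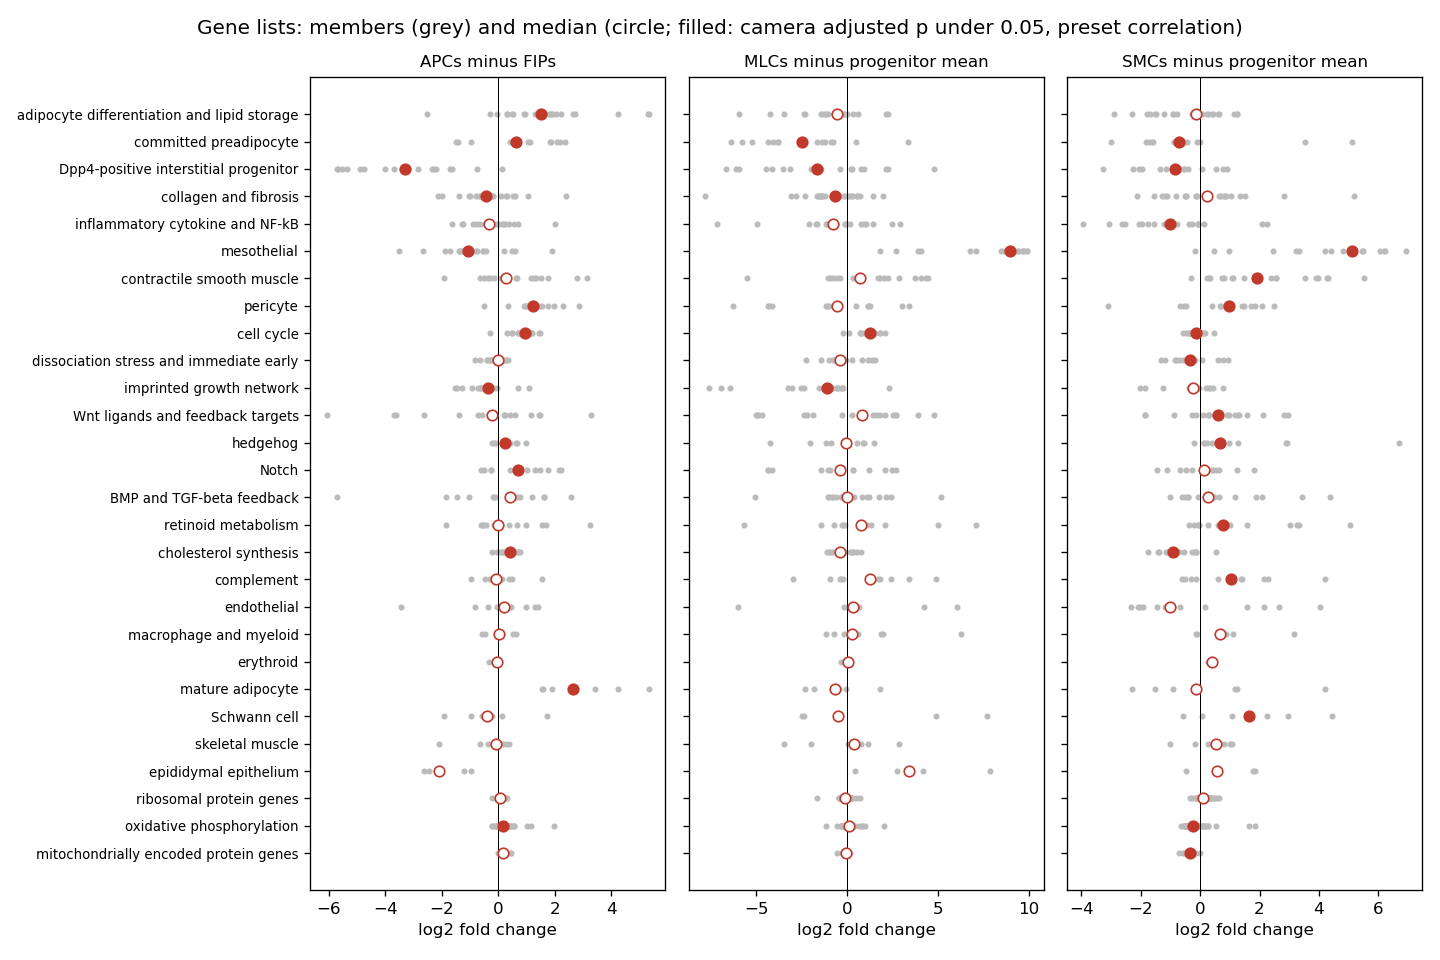
Log2 fold changes of the gene lists' measured members (grey points) and their medians (circles, filled where camera with the preset correlation gave an adjusted p under 0.05) in the 3 main comparisons. The mesothelial list had the largest medians, 8.97 in MLCs and 5.10 in SMCs, and the interstitial progenitor list the lowest in APCs against FIPs, -3.30.

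Each population also had genes of its own, called higher there than in each of the other 3. There were 161 in APCs, 226 in FIPs, 1597 in MLCs and 413 in SMCs. The 5 leading genes of APCs were Plin1, Car3, Lgals12, Mlxipl, coding for a carbohydrate-responsive transcription factor, and Tshr, the thyrotropin receptor gene, with Tshr at 124 ± 23.7 normalized counts in APCs and at 12.4 or less on average elsewhere. Those of FIPs were Akr1c18, Efhd1, Ly6c1, Ackr2 and Ly6a, coding for the stem cell antigen Sca-1, with Ly6a at 9256 ± 1053 in FIPs, 740 ± 332 in APCs, 759 ± 285 in SMCs and 177 ± 116 in MLCs. The leading MLC genes were Sim2, coding for a transcription factor (Entrez gene 20465; chromosome 16, 94085104 to 94127032), Krt14, Agr2, Il18r1 and Slpi. Sim2 was at 572 ± 57.1 in MLCs and at 1.90 or less on average in the others, and Agr2 at 374 ± 55.6 in MLCs and listed at 0 in every APC library. The leading SMC genes were Hhip, Elfn2, Col9a1, Itgbl1 and Tspan11, with Tspan11 at 2508 ± 370 in SMCs and at 78.3 or less on average elsewhere, and Col9a1 at 279 ± 80.8 in SMCs and listed at 0 in every MLC library. With a filter at 50 the number of SMC genes was 271, and with equal totals the number of FIP genes was 148.

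**Figure D4:**
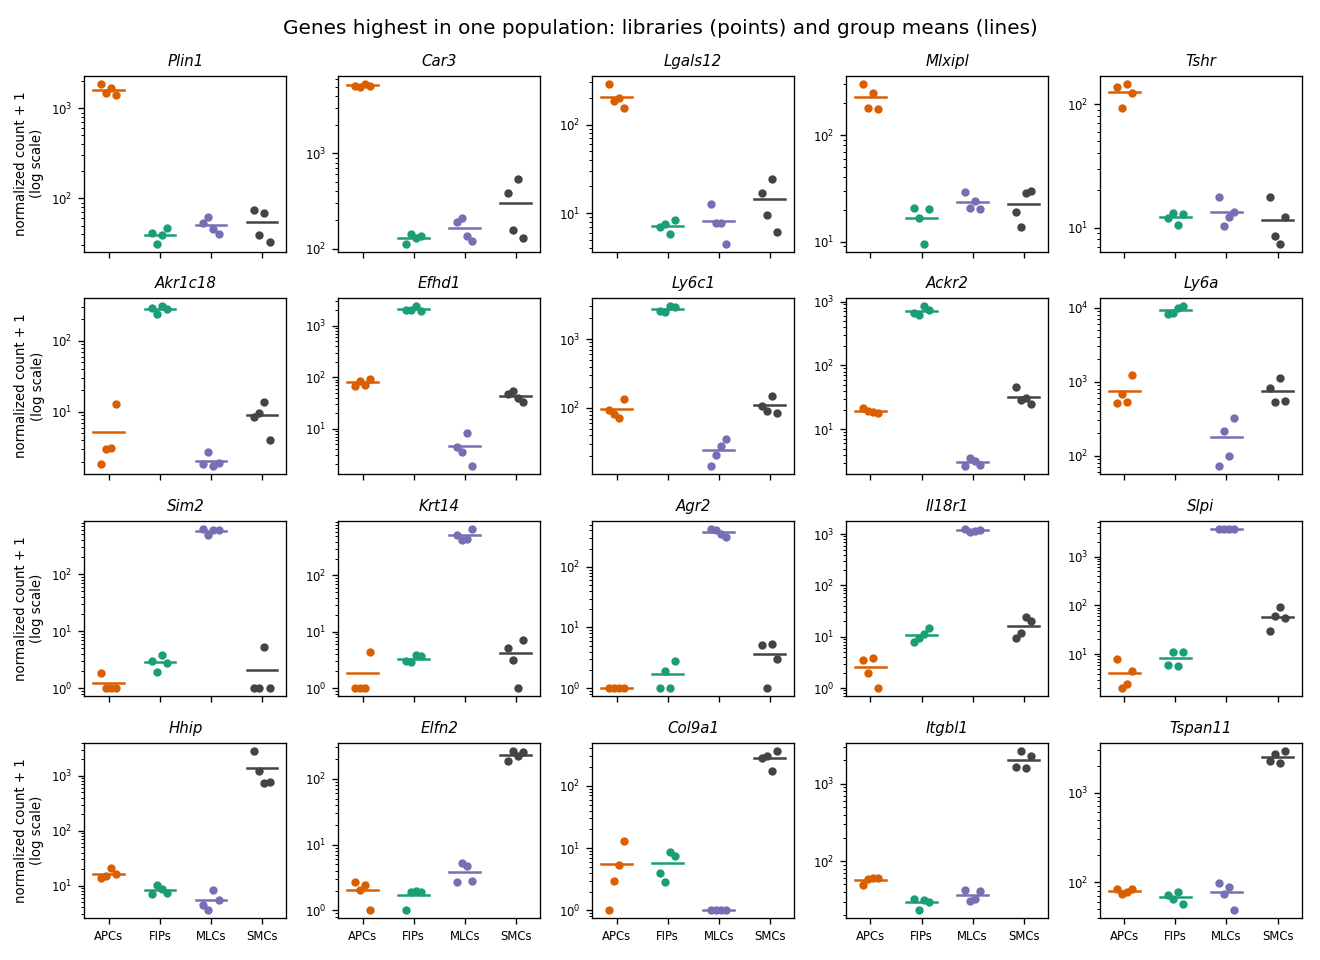
Normalized count + 1 (log axis) of the 5 leading genes of each population, one row of panels per population; points are the 16 libraries and lines the group means. In every panel the 4 libraries of the leading population lie above the other 12.

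Markers of cell types outside the sorted populations were low or uneven. Of 14 endothelial genes, Tek, coding for the angiopoietin receptor, averaged 7827 in FIPs and 719 in APCs (log2 fold change -3.44), Kdr and Esam rose in MLCs by 4.25 and 6.03, and Cdh5, Kdr and Esam rose in SMCs by 4.05, 2.67 and 2.17, while Pecam1, the general endothelial marker, averaged 102 or less in every population. The endothelial counts were 2 higher and 1 lower in APCs, 2 and 1 in MLCs and 4 and 6 in SMCs (7 lower adjusted over the list alone, the other counts the same), and no group call was made (adjusted p = 0.69, adjusted p = 0.676 and adjusted p = 0.675). Csf1r, the macrophage growth factor receptor gene, rose in MLCs by 6.28 and in SMCs by 3.16, with 3 of 8 macrophage genes higher and 1 lower in MLCs and 2 higher in SMCs (adjusted p = 0.474 and adjusted p = 0.127), and none called between APCs and FIPs (adjusted p = 0.884). Mbp and Erbb3 of the Schwann cell list rose in MLCs by 7.71 and 4.88 and in SMCs by 4.45 and 2.97. 2 of its 6 genes rose and 2 fell in MLCs (adjusted p = 0.95, median -0.50, mean 1.12 and a downward test), 4 rose in SMCs (adjusted p = 0.0465, and adjusted p = 0.174 with an estimated correlation) and 1 rose and 1 fell in APCs (adjusted p = 0.242). Without APCs replicate 1, SMCs replicate 2 or SMCs replicate 4 the SMC Schwann call was lost, at adjusted p up to 0.0614, as it was with a pseudocount of 0.1 (adjusted p = 0.0514) and with equal totals (adjusted p = 0.0603). Above the progenitor mean, SMCs held 10.4% of the MLC level of Mbp and 10.6% of that of Csf1r, against a median of 9.05% over 104 genes high in MLCs and near absent in progenitors. Among 7 mature adipocyte markers, Cfd and Adipoq rose in SMCs by 4.19 and 1.25 (Adipoq by 0.89 without SMCs replicate 3 and 0.91 with quantile normalization, under the fold limit) and Plin1 fell, 3 higher and 2 lower (adjusted p = 0.797, median -0.15, mean 0.25 and a downward test), and in MLCs 1 rose and 2 fell (adjusted p = 0.311). These changes are from the mean of progenitors that were themselves unlike. Adipoq averaged 261 in APCs and 12.5 in FIPs. Plin1 was at 1607 in APCs, 38.7 in FIPs and 53.0 in SMCs. Epididymal epithelium genes summed to 687 ± 153 in MLCs, 58.4 ± 20.96 in SMCs, 51.0 ± 44.4 in FIPs and 9.11 ± 0.72 in APCs, and 4 of 5 rose in MLCs, among them Krt14 (7.87) and Epcam (4.15), 2 rose in SMCs and 3 fell in APCs (adjusted p = 0.153, adjusted p = 0.5 and adjusted p = 0.138). With equal totals that list was called in APCs against FIPs. Skeletal muscle genes had 1 of 6 lower in APCs, 1 higher and 2 lower in MLCs and 1 higher and 1 lower in SMCs (adjusted p = 0.591, adjusted p = 0.868 and adjusted p = 0.78; in MLCs the median was 0.40, the mean -0.12 and the test downward), and none of 3 measured erythroid genes was called in any of the 3 comparisons (adjusted p = 0.884, adjusted p = 0.95 and adjusted p = 0.677; in MLCs the median was 0.05, the mean -0.07 and the test downward). The lymphocyte list, with too few genes past the filter for a test, summed to between 26.2 and 37.0 on average in each population. These counts for the macrophage, Schwann, adipocyte, epithelial, muscle and erythroid lists were the same adjusted over the list alone.

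Single ribosomal and respiratory genes were seldom called. None of 85 genes of the ribosomal protein list was called between APCs and FIPs or in SMCs, and only Rps4l fell, by 1.65, in MLCs, over all genes and adjusted over the list alone (adjusted p = 0.0823, adjusted p = 0.0696 and adjusted p = 0.058). Rps4l, in the list by its name, is annotated as a transcribed pseudogene. As single libraries were left out, the adjusted p of the ribosomal list lay between 0.00387 and 0.728, 0.011 and 0.305, and 0.023 and 0.279 in these comparisons. It passed 0.05 without any 1 of APCs replicates 1 and 2 and FIPs replicate 4 in the first, of APCs replicates 3 and 4, FIPs replicate 4, MLCs replicate 1 and SMCs replicates 1 and 3 in the second, and of APCs replicates 1 and 2, FIPs replicates 1 and 3 and MLCs replicates 2, 3 and 4 in the third. With quantile normalization the list was called in the first (adjusted p = 0.000134) and second (3.39e-05), with equal totals too (0.0022 and 0.0187). With the replicate number as a block it was called in all 3 comparisons. Of 78 oxidative phosphorylation genes 3 rose in APCs, 1 rose and 1 fell in MLCs (1 and 0 adjusted over the list alone, the other counts the same) and 2 rose in SMCs. As a list they lay higher in APCs than in FIPs (adjusted p = 0.000122, and adjusted p = 0.595 with an estimated correlation) and lower in SMCs than in progenitors (adjusted p = 9.26e-05, and adjusted p = 0.507 with an estimated correlation), with no call in MLCs (adjusted p = 0.834). Cox6b2 rose in all 3 comparisons, by 1.17, 2.04 and 1.64, the first at 0.97 and not called with quantile normalization. Of the mitochondrially encoded genes, mt-Rnr1 and mt-Rnr2 were not called (adjusted p = 0.983, adjusted p = 0.95 and adjusted p = 0.709), and the 10 measured protein genes, a list added after the data were seen, were at a median log2 fold change of 0.18 in APCs, -0.07 in MLCs and -0.34 in SMCs with none called (adjusted p = 0.322, adjusted p = 0.721 and adjusted p = 0.0466, and adjusted p = 0.655 with an estimated correlation for SMCs). The SMC call was lost without any 1 of APCs replicates 1 and 4, FIPs replicates 1 and 2 and SMCs replicates 1, 2 and 4 (left-out range 0.00545 to 0.0752), with a pseudocount of 0.1 (0.0514) and with quantile normalization (0.243). In APCs the list was called without APCs replicate 2 (0.0228). They made up between 0.613% and 1.20% of the values of each library.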

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

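The tests of the 3 patterns weighed here, with the limits that decided them, were chosen only after the values concerned had been seen. In each group of 4 libraries the highest or lowest library was held apart from the rest when its gap to the nearest other passed Dixon's 95% critical value as a share of the group's range, over 207 named genes and the library measures. Of 783 groups 41 passed, against 39.15 from chance, which sets apart about 1 in 20 groups of normal values. The total is therefore no more than chance gives under that assumption. The groups hold chosen genes that can move together, so the total does not tell whether a single gap, or a run of gaps in 1 library, is chance. The library set apart most often was APCs replicate 4, with 11 of them.

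In APCs replicate 4 the gap was 0.971 of the range for Acta2, at 2388 normalized counts against 155.8 to 221.4 in the others, 0.949 for Aldh1a2, 0.937 for Cfd, 0.931 for Tpm2, 0.914 for Ezr, 0.888 for Ltbp2, 0.885 for Cfb, 0.882 for Tnc and 0.85 for Il33, all higher there. It was lower for Fbn1 (0.927) and Cebpa (0.84). APCs replicate 1 was high for Esam (0.989) and low for Itgbl1 (0.917), and APCs replicate 2 was low for Dhrs3 (0.884) and Cidec (0.841) and high for Sqle (0.856). Among FIPs, replicate 2 was low for Dpt (0.95), Nkain4 (0.911), Dpp4 (0.863) and Vcam1 (0.848) and high for Smoc1 (0.838), replicate 1 was high for Gucy1b1 (0.917) and low for Ednra (0.837), and replicate 4 was low for Sqle (0.951), Hspa1a (0.921) and Mcm6 (0.899). Among MLCs, replicate 2 was high for H19 (0.905), Mcm4 (0.864) and Boc (0.861) and low for Pkhd1l1 (0.891), replicate 1 was high for Ebf2 (0.926) and Mylk (0.861), and replicate 4 for Cd9 (0.896), Il6 (0.845) and Krt8 (0.83). Among SMCs, replicate 3 was high for Uty (0.894), Edn1 (0.873) and Pparg (0.853) and low in reads (0.838), with 9.20 M against 17.91 M or more, replicate 2 was high for Mmd2 (0.912) and replicate 4 for Gdf10 (0.898).

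SMC libraries held mesothelial transcripts well above the progenitor level. Over 104 genes high in MLCs and near absent in progenitors, the SMC level was a median 9.05% of the MLC level (quartiles 6.74% and 11.6%); Upk3b was at 3528 normalized counts in SMCs and 40551 in MLCs. Reads of MLCs spread alike over all libraries would reach the progenitor libraries too. As the whole cause they are argued against by the pattern itself and not by a separate test. In SMCs 17 of the 20 mesothelial genes, all of them measured here, were over 2 times both progenitor means. Whether MLC cells are the whole cause stays open. Of the 104 genes 12 lay over 1.5 times above their library's median share in all 4 SMC libraries and 9 (8.65%) as far below. Genes above need only some expression in SMCs, and the test takes carried cells to have the average MLC profile. A first form of the test counted genes off either way, 21 (20.2%), and went against MLC cells as the whole cause. It was then changed to count only genes below. The lowest mean shares were 0.826% for Il18r1, 1.43% for Slpi, 2.11% for Krt18 and 2.42% for Chst4. Carried cells of the average profile alone would not give shares this low, but most of the 104 genes were not so far below. The 15 of the 104 genes on the mesothelial list had their highest median share in SMCs replicate 3 (10.5%) and their lowest in SMCs replicate 4 (5.55%). Of the other 89 genes 93.3% were at a larger share in replicate 3, as a share of such cells that varies between libraries needs. Shared regulation would also give that. Carry-over as a part or the whole of the signal and expression by the SMC-sorted cells themselves both stay open, and a difference between the populations was not tested apart from these. MLCs were among the Pdgfrb-expressing cells sorted, and the gates that parted them from SMCs are not given in the labels.

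APCs replicate 4 had 21 genes at least 4-fold above each other APC library, such as Cxcl14 (1707 against a mean of 47.6), Tagln (1463 against 264) and Acta2, with a median log2 difference of 3.72. Transcript length is argued against, since the median was 3.82 once the trend with length was removed. After the other libraries were thinned to its depth, 18 of the 21 stayed 4-fold above. That cannot decide on lower depth, because the genes were picked as 4-fold above and thinning leaves expected normalized values unchanged. SMC-sorted cells in bulk are argued against by a narrow margin: the 21 genes reached a median 74.4% of the SMC level (lower quartile 60.9%), and 27 genes highest in SMCs, chosen in a fit without this library after a first choice had left out raised genes, a median of 1.05% (90th percentile 59.0%). The 21 were picked as raised in this library, and all 21 were higher in SMCs than in the other APC libraries. Emb, S100a4, Cxcl14, Acta2 and Inhba are in both sets. Of the 27 genes 23 lay under 20%, and Emb, S100a4, Cxcl14 and Acta2 reached 50.5% to 82.7%. Hmcn1 was at 1086 against 1864 in the other APC libraries and 20249 in SMCs. A subset of the SMC-gated cells may be present and stays open, as does a state of the precursors themselves, and no biological explanation was tested because the design gives none for 1 library.

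Single endothelial-list genes were high in sorted populations: Tek in FIPs, Kdr and Esam in MLCs and Cdh5 in SMCs. These genes were picked as high members, so a lead over the rest of the list was close to given. Endothelial cells as the whole cause are argued against in each case, because most other genes of the list did not move with them. Of the others, 0 of 13 were called higher in FIPs than in APCs, and 0 of 12 were called higher in MLCs. In SMCs Kdr, Esam and Emcn were higher beside Cdh5, 3 of the other 13 genes, and 6 were lower, among them Pecam1 (-1.91). The others' median log2 fold change was -0.22 in FIPs against APCs, where Tek differed by 3.44, 0.29 in MLCs, where Kdr rose by 4.25, and -1.14 in SMCs, where Cdh5 rose by 4.05. Expression by the sorted cells is a hypothesis that these data leave open, and a difference between the populations in these genes is what the design compares.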

How the results depend on the processing

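Leaving out 2 libraries together, the edgeR fit and the limits for the tests on splits of the libraries were written down after the data had been seen, and the other alternatives were planned. No result reversed in direction. Of 336 counts under alternatives 322 stayed within 1.5 times, of 2001 list results 1870 kept their side of the threshold, 85 lost it and 46 gained it, and of 16758 values of named genes 16521 kept theirs, 133 lost it and 104 gained it. With a filter at 50 the genes highest in SMCs numbered 271, because fewer genes were tested, and with equal totals those highest in FIPs numbered 148, for which the cause was not tested. With no fold limit, which admits smaller changes by construction, the counts were 6168 between APCs and FIPs, 10139 between APCs and MLCs, 8439 between APCs and SMCs, 10093 between FIPs and MLCs, 8108 between FIPs and SMCs, 9854 between MLCs and SMCs, 10558 for MLCs and 8673 for SMCs against the progenitor mean, and 905, 1296, 3423 and 1154 highest in APCs, FIPs, MLCs and SMCs. As single libraries were left out the 12 counts, in that order, lay at 1484 to 1609, 4381 to 4458, 2473 to 2702, 4605 to 4709, 2559 to 2767, 4105 to 4232, 4458 to 4533, 2441 to 2606, 148 to 163, 209 to 232, 1562 to 1605 and 379 to 433. With edgeR on 14 libraries they were 1499, 4396, 2442, 4700, 2747, 4259, 4534, 2516, 168, 227, 1566 and 429.

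Replicate numbers were tried as a block. The 24 pairs of libraries with the same number correlated at -0.034 to 0.171 after group means were removed, 6 of them over 0.1, and 8 of the 16 libraries correlated best with their own number, so by the rule set beforehand the number was not taken to pair them, although interferon genes, described under the other observations, moved with it. The rule does not exclude a shared source, since all same-number correlations but that of MLCs and SMCs replicates 2 (-0.034) were positive. The block gave 1567, 4452, 2598, 4680, 2710, 4211, 4529, 2536, 160, 224, 1613 and 414. It moved list results near the threshold: the ribosomal list was called in APCs against FIPs (adjusted p = 0.04), MLCs (0.0212) and SMCs (0.0293), the adipocyte list in MLCs (0.0344) and the BMP and TGF-beta list in SMCs (0.0437), and the hedgehog list was not called in APCs (0.054). Under at least 1 alternative 14 of 102 named calls were lost in APCs against FIPs, 14 of 151 in MLCs and 14 of 121 in SMCs. Those with a printed change include H19 (-0.58) and Cox6b2 (0.97) in APCs, Zfp36 in MLCs (-0.89) and Igf2 (-0.88) and Adipoq (0.91) in SMCs with quantile normalization, Hsd17b7 in MLCs (-0.88) with equal totals, and Krt18 in APCs (-0.91) and Hey2 in SMCs (0.95) with a pseudocount of 8. Low genes rest on few reads, and with a pseudocount of 8, which shrinks their changes, the count between APCs and FIPs was 1175.

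A chance division of the libraries is argued against for all 12 counts, since no other division tried gave as many genes. The splits cannot tell a difference between populations from one between single sorts or animals, which the labels do not give. Other divisions mix the sorted populations, which widens the spread within groups, so their low counts are not a rate of false calls. Of 35 splits of the 8 libraries of each pair, only the real 1 gave as many genes, with highest others of 5, 0, 72, 1, 1 and 0 against 1566, 4440, 2590, 4671, 2693 and 4185. For each of the rest 100 splits were used, the real 1 included and the others drawn, and again only the real 1 gave as many. The highest others were 2406 against 4520 for MLCs and 932 against 2524 for SMCs, and 0 against 161, 226, 1597 and 413 for the genes highest in each population.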

Other observations

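The test of interferon genes given here was chosen after their values had been seen, and the 3 gene lists described first were planned. Complement genes were higher in SMCs than in progenitors, 6 of 11 with none lower and the same adjusted over the list alone (camera adjusted p = 0.037, and adjusted p = 0.507 with an estimated correlation; 0.0538 without APCs replicate 1 and 0.064 with equal totals). C2, coding for a protease of the classical pathway, rose by 2.29 on the log2 scale, C7, a part of the membrane attack complex, by 2.16 and Cfb, coding for factor B, by 1.37 (limma, Benjamini-Hochberg). In MLCs 6 of 11 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.64): C2 rose by 4.88, Cfb by 3.42 and C3, the central component, by 2.40, and C7 fell by 2.96. C2 and Cfb were higher in MLCs than in SMCs, and SMC libraries held a median of 9.05% of the MLC level, above the progenitor mean, over 104 genes high in MLCs and near absent in progenitors. Between APCs and FIPs none was called by limma over all genes or adjusted over the list alone (adjusted p = 0.591; median log2 fold change -0.08, mean 0.02 and a downward test), with Cfb at -0.95.

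Retinoid genes differed by population in which enzyme was high. Aldh1a2, coding for the retinaldehyde dehydrogenase of mesothelium, rose in MLCs by 7.09, while Aldh1a3, its sister enzyme, fell by 5.65 there and was lower in APCs than in FIPs (-1.85). Of 14 retinoid genes 6 rose in SMCs and none fell (adjusted p = 0.00417, and adjusted p = 0.241 with an estimated correlation), with the retinoic acid carrier gene Crabp2 at 3.32 and Dhrs3, coding for a retinal reductase, at 1.59. The list summed to 21025 ± 605 in MLCs and 13693 ± 908 in SMCs. Above the progenitor mean, SMCs held 23.9% of the MLC level of Aldh1a2, against the median of 9.05% given for 104 genes high in MLCs. In MLCs 5 rose and 2 fell (adjusted p = 0.311), and in APCs against FIPs 4 rose and 1 fell (adjusted p = 0.591, median -0.01, mean 0.32 and an upward test), among them Crabp1 (3.27). These counts were the same adjusted over the list alone. Cholesterol synthesis genes, lower in SMCs, lay higher in APCs than in FIPs as a list with none of 20 past the fold limit (adjusted p = 0.000115, and adjusted p = 0.302 with an estimated correlation), such as Cyp51 at 0.75 and Sqle at 0.71. In MLCs Hsd17b7 alone fell by 1.09 (-0.88 and not called with equal totals; adjusted p = 0.129), and the list alone gave the same counts in both comparisons.

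Interferon-stimulated genes were higher in the library numbered 4 of each population. In APCs replicate 4, 12 such genes were seen first, and 28 others had a median log2 difference of 0.72 from the other APC libraries, with 27 of the 28 higher. The medians of the libraries numbered 4 were 0.72 in APCs, 0.81 in FIPs, 1.21 in MLCs and 0.43 in SMCs, and the other 12 libraries lay between -0.51 and -0.01. Of 13824 orders of the numbers within populations 18 gave as large a spread between numbers (exact permutation test, p = 0.0013). A candidate explanation is that libraries of the same number came from the same animals or day, which the labels do not give, and the test cannot tell an animal from a batch.

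The Y chromosome genes Ddx3y, Eif2s3y and Uty were at 2477 to 3975, 740 to 1077 and 330 to 454 normalized counts in the 16 libraries, and Xist, the X-inactivation RNA, at 0 to 8.90.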
